A study of Mus musculus with 11 samples.

How the data were processed

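RNA sequencing was analysed in 11 libraries from 6 mice of 8 weeks: uninjured and injured heart regions of C57BL/6J (B6, n = 3 of each) and C3H/HeJ (C3H, n = 3 uninjured and n = 2 injured). Per the labels, total RNA was extracted with a column kit and libraries followed standard Illumina preparation, and the titles name day 7. The way the hearts were injured is not given in the sources used here. The authors aligned reads with TopHat2 2.0.11 to mouse build mm9, counted them with HTSeq 0.6.1 and normalised them with DESeq, and the gene annotation, strandedness, filters and the DESeq version are not given in the sources used here. The deposited signal of each library is its gene-level read counts divided by 1 size factor. All values of a library were whole multiples of 1 step, the inverse of its size factor (100% at a tolerance of 1e-06), and factors recomputed by median of ratios from the reads so recovered equalled those of the authors. These multiples gave 9699985 to 22138459 reads per library. The table held 15274 genes, named by symbol only, with no mitochondrially encoded genes. No coordinates are given, since the reference at hand is of build GRCm38 and not mm9. Build mm9 is of B6, so that C3H reads over variants can be undercounted, which acts on comparisons between strains and cancels in the injury effects where it is equal in both regions.

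Choices of groups, comparisons, gene lists, naming rule and most alternatives were made before the data were examined, and the exceptions are named where they are used. Values were analysed as log2(normalised count + 1), which understates fold changes of genes with low counts. Genes with at least 10 in at least 2 libraries were tested (14751 tested, 523 not). A linear model with 4 group means over all 11 libraries was fitted with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend, 7 residual degrees of freedom), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on two-sided p. The 5 comparisons were injury within each strain, the difference of these effects between the strains (the interaction term), and C3H against B6 in uninjured and in injured regions. The correlation of the injury effects of the strains was computed across genes, with a jackknife over libraries for its SE.

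Samples of the same number within a strain were taken as regions of the same heart, as the labels name the mouse, which gave 5 animals with both regions. Residuals of the regions of an animal correlated at 0.276, -0.0140 and 0.524 in B6 and at 0.305 and 0.575 in C3H, and at 0.392 in a fit with animal as a random block. The fit without animals was the planned one, and blocked fits (fixed, with 3 residual degrees of freedom, and random) were alternatives.

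There were 32 gene lists, 15 of pathways (osteogenic, chondrogenic, mineralization inhibitors and phosphate, osteoclast, extracellular matrix, matrix remodelling, myofibroblast and TGF-beta, Wnt, inflammatory cytokines, interferon response, cell cycle, fatty acid oxidation, oxidative phosphorylation and TCA cycle, glycolysis and hypoxia, cardiac stress) and 17 of markers (cardiomyocyte, fibroblast, macrophage and monocyte, neutrophil, T and NK cell, B cell, mast cell, endothelial, mural, epicardial, adipocyte, Schwann cell, erythroid, skeletal muscle, atrial, lung epithelium, cartilage and bone). Of 526 symbols, 481 were found, 3 of them through RefSeq synonyms, and the other 45 were not analysed here. Of 469 list genes tested, 14 were in more than 1 list. Lists of at least 5 tested members (29) were tested against all other genes with limma's camera, with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. With the preset correlation 18 lists passed in B6, 15 in C3H, 12 for the interaction, 12 in uninjured and 8 in injured regions, and with the estimated correlation 0 passed in each. Counts of members are given over all genes tested and adjusted over the list alone.

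Genes were named by rule: for each comparison the 4 with the largest increase and the 4 with the largest decrease among those past the threshold with a mean of at least 50 and no overlap between groups, without predicted genes, clones, histones and small RNAs. Added to these were, for the injury effects and the interaction, the 2 members of each pathway list with the largest change past the threshold or else the 1 with the smallest p, the most abundant member of each marker list, and Enpp1, Spp1, Runx2, Alpl, Bglap, Abcc6, Tlr4, Nnt, Postn, Col1a1, Myh6 and Nppa where they were tested. List members named to show which genes moved were chosen after their values were seen. Where a group held at most 3 reads of a gene, no fitted fold is given: with 0 reads the fold is a bound against 3 reads over the group, and with 1 to 3 reads a ratio of depth-scaled reads with an exact 95% interval. These bounds and intervals cover counting error only.

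Alternatives were pseudocounts of 0.5 and 5, no filter, a mean of at least 50, TMM rescaling, quantile normalization, limma without trend or with array weights, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, only the groups compared, each library left out in turn, and the animal as a block. In a fit that left 1 library in a group, that library was assumed to vary like the others. On data simulated from the mean and dispersion of each gene over these libraries, with 100 genes of a mean above 50 changed at each size, limma recovered 18% of 2-fold and 86% of 4-fold changes in a design like that of B6, and 9% and 75% in one like that of C3H, and 7.14% and 7.69% of its calls were false.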

Results

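Gene expression was measured by RNA sequencing in uninjured and injured pieces of mouse hearts from C57BL/6J (B6) and C3H/HeJ (C3H) mice, the latter an inbred strain known for dystrophic calcification of the heart. The libraries were titled day 7 and came from mice of 8 weeks. They formed 4 groups: B6 uninjured (n = 3), B6 injured (n = 3), C3H uninjured (n = 3) and C3H injured (n = 2), 11 libraries from 6 animals. Between 9699985 (B6 uninjured library 2) and 22138459 (C3H uninjured library 3) reads were assigned to genes per library. The first principal component held 38.6% of the variance and set the C3H injured libraries (scores 88.1 and 102) apart from all the others (-68.7 to 33.1). The second held 25% and parted the strains, with B6 libraries from 5.28 to 54.4 and C3H libraries from -73.3 to -11.0. Changes below are log2 fold changes of normalised counts with their standard error (SE), and n is as above unless stated. All 5 C3H libraries had high Xist and near-zero counts of Y-linked genes, and all 6 B6 libraries the reverse. Strain could therefore not be told apart from sex in any comparison between strains.

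The first comparison asked which genes differed between injured and uninjured regions of B6 hearts. Thbs4, which encodes a secreted matrix glycoprotein, rose by 4.15 (SE 0.36, adjusted p = 0.00114), from a mean normalised count of 160.5 to 2854. Angptl7, an angiopoietin-like secreted protein, rose by 2.32 (SE 0.27, adjusted p = 0.0115), from 78.0 to 393. Both genes were higher in 3 of 3 injured libraries than in any uninjured library. They were the 2 genes past the threshold of 14751 tested, with 2 up and 0 down. The Angptl7 call was lost without B6 uninjured library 1 (adjusted p = 0.116), B6 uninjured library 2 (0.100), B6 injured library 1 (0.0578), B6 injured library 2 (0.0953) or B6 injured library 3 (0.0560). This call was also lost with only the groups compared (adjusted p = 0.0541).

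With limma 1979 genes had an unadjusted p under 0.05 in B6. Array weights gave 1387 up and 1321 down in a fit that had not converged, and weights gene by gene 133 up and 91 down. With edgeR 2 genes were called too, whereas DESeq2 called 31 up and 14 down and limma on quantile-normalised values 2 up and 1 down. With the animal as a block the count was 20, of which 17 rose and 3 fell, and these 20 included the 2 above. Among these 20, named here after their values were seen, were the matrix genes Fmod (3.61, SE 0.32) and Cilp (2.50, SE 0.35) and the contractile gene Cnn1 (2.14, SE 0.31). Myeloid genes among them were Gpnmb (2.61, SE 0.26), Itgax (1.80, SE 0.26) and Trem2 (1.09, SE 0.17). The 3 that fell with the block were the homeobox genes Irx1 (-4.03, SE 0.44) and Irx5 (-2.33, SE 0.26) and the natriuretic peptide receptor gene Npr3 (-1.68, SE 0.23). Without the block adjusted p was 0.0800 for Fmod, 0.323 for Cilp, 0.105 for Cnn1, 0.279 for Gpnmb, 0.307 for Itgax and 0.364 for Trem2. It was 0.322 for Irx1, 0.0584 for Irx5 and 0.364 for Npr3. Col9a2, a cartilage collagen gene, had 1 read over the 3 B6 uninjured libraries. Its injured-to-uninjured ratio was 89.1 (95% counting interval 15.8 to 3543). That ratio was 54.4 without B6 uninjured library 3, and without B6 uninjured library 1 it had 0 reads there and was at least 18.2-fold higher. It had adjusted p = 0.137 without the block, and adjusted p = 0.0233 with it.

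Matrix lists were higher in injured B6 regions with the preset correlation only. All 25 extracellular matrix list genes were higher, with a median of 1.02 (adjusted p = 6.41e-08, and adjusted p = 0.337 with an estimated correlation). Of them 0 passed over all genes and 1 adjusted over the list alone. The 23 myofibroblast and TGF-beta genes were all higher too, with a median of 0.97 (adjusted p = 5.57e-11, and adjusted p = 0.203 with an estimated correlation). Among these 12 passed when adjusted over the list alone against 0 over all genes. Of the matrix remodelling genes, 21 of 22 were higher (median 0.79, adjusted p = 7.67e-06, and adjusted p = 0.286 with an estimated correlation). No single one passed on either adjustment. Chondrogenic genes had a median of 1.64 over 12 members (adjusted p = 7.45e-06, and adjusted p = 0.203 with an estimated correlation). Among these 3 passed adjusted over the list alone and 0 over all genes. Fibroblast markers had a median of 0.58 (adjusted p = 0.00116, and adjusted p = 0.370 with an estimated correlation), or 0.88 and 0.36 without B6 uninjured libraries 1 and 2. Single genes that missed the threshold included Postn at 1.06 (SE 0.59, adjusted p = 0.437), Col1a1 at 0.96 (SE 0.84, adjusted p = 0.601) and the collagenase gene Mmp2 at 0.93 (SE 0.25, adjusted p = 0.364).

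Lists of mitochondrial metabolism were lower in injured B6 regions, again with the preset correlation only. All 25 oxidative phosphorylation and TCA cycle genes were lower, with a median of -0.80 (adjusted p = 4.30e-13, and adjusted p = 0.253 with an estimated correlation). Of them 17 passed adjusted over the list alone against 0 over all genes. Of the fatty acid oxidation genes, 22 of 23 were lower (median -0.57, adjusted p = 7.97e-09, and adjusted p = 0.203 with an estimated correlation). Of them 7 passed adjusted over the list alone and 0 over all genes. Cardiomyocyte markers were lower with them, in 22 of 24 genes, with a median of -0.54 (adjusted p = 2.38e-05, and adjusted p = 0.203 with an estimated correlation). After quantile normalization the median of cardiomyocyte markers was -0.08 and that of oxidative phosphorylation genes -0.44. Myh6, the alpha myosin heavy chain, was at -0.63 (SE 0.40, adjusted p = 0.483), and at 0.01 with that normalization. Cardiac stress genes had a median of 0.53 (adjusted p = 0.000196, and adjusted p = 0.203 with an estimated correlation). In this list the atrial natriuretic peptide gene Nppa was at 1.98 (SE 0.65, adjusted p = 0.364) and Gdf15 at 2.39 (SE 0.54, adjusted p = 0.364).

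Some immune lists and that of the cell cycle were higher in injured B6 regions with the preset correlation only. The neutrophil (median -0.23) and mast cell lists (0.39) did not pass. Macrophage and monocyte markers had a median of 0.69 over 21 genes (adjusted p = 7.95e-07, and adjusted p = 0.253 with an estimated correlation). Of them 5 passed adjusted over the list alone against 0 over all genes. The median was 1.20 for T and NK cell markers (adjusted p = 0.00786, and adjusted p = 0.303 with an estimated correlation). It was 0.74 for B cell markers (adjusted p = 0.00708, and adjusted p = 0.286 with an estimated correlation) and 0.55 for inflammatory cytokines (adjusted p = 0.00842, and adjusted p = 0.427 with an estimated correlation). Interferon response genes had a median of 0.36 (adjusted p = 0.00708, and adjusted p = 0.522 with an estimated correlation). Cell cycle genes had 0.75 (adjusted p = 0.000432, and adjusted p = 0.433 with an estimated correlation) and Wnt genes 0.59 (adjusted p = 0.00478, and adjusted p = 0.321 with an estimated correlation). The Wnt median was 0.31 after quantile normalization and 0.92 without B6 injured library 3. Epicardial markers had a median of 0.71 (adjusted p = 0.000576, and adjusted p = 0.321 with an estimated correlation) and mural cell markers 0.37 (adjusted p = 0.0496, and adjusted p = 0.431 with an estimated correlation). The preset-correlation call was lost for cytokines without B6 uninjured library 3, or B6 injured library 1 or 2 (adjusted p up to 0.575) and for interferon genes without B6 uninjured library 3 or B6 injured library 2 (adjusted p up to 0.444). It was likewise lost for mural cells without B6 uninjured library 1 or 2, or B6 injured library 3 (adjusted p up to 0.162) and for epicardial markers without B6 uninjured library 1 (adjusted p = 0.0963). Medians without 1 library were 0.44 without B6 uninjured library 3 for macrophages, 0.08 without B6 uninjured library 3 and 0.77 without B6 injured library 2 for T and NK cells, 0.29 without B6 uninjured library 3 for cytokines and 0.09 without B6 uninjured library 3 and 0.14 without B6 injured library 2 for interferon genes. They were 0.37 without B6 uninjured library 3 for the cell cycle, 0.34 and 1.24 without B6 uninjured libraries 1 and 2 for epicardial and 0.18 and 0.64 without B6 uninjured libraries 2 and 3 and 0.58 and 0.24 without B6 injured libraries 1 and 3 for mural cell markers. Without B6 uninjured library 3, the call was also lost for Wnt genes (adjusted p = 0.0856), the cell cycle (adjusted p = 0.214), T and NK cells (adjusted p = 0.214) and B cells (adjusted p = 0.0826).

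Bone-related lists did not pass in B6. Osteogenic genes had a median of 0.20, or 0.11 after quantile normalization (adjusted p = 0.0541, and adjusted p = 0.321 with an estimated correlation). Osteoclast genes had 0.49 (adjusted p = 0.0528, and adjusted p = 0.439 with an estimated correlation) and inhibitors of mineralization 0.23 (adjusted p = 0.179, and adjusted p = 0.321 with an estimated correlation). With the animal as a block the osteogenic list (adjusted p = 0.0488) and the osteoclast list (adjusted p = 0.0292) passed with the preset correlation. Spp1, which encodes osteopontin, was at 0.77 (SE 0.53, adjusted p = 0.510). Runx2, a transcription factor of osteoblast differentiation, was at 0.76 (SE 0.26, adjusted p = 0.364). Enpp1, an ectoenzyme that makes pyrophosphate, was at 0.86 (SE 0.34, adjusted p = 0.364).

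**Figure D1:**
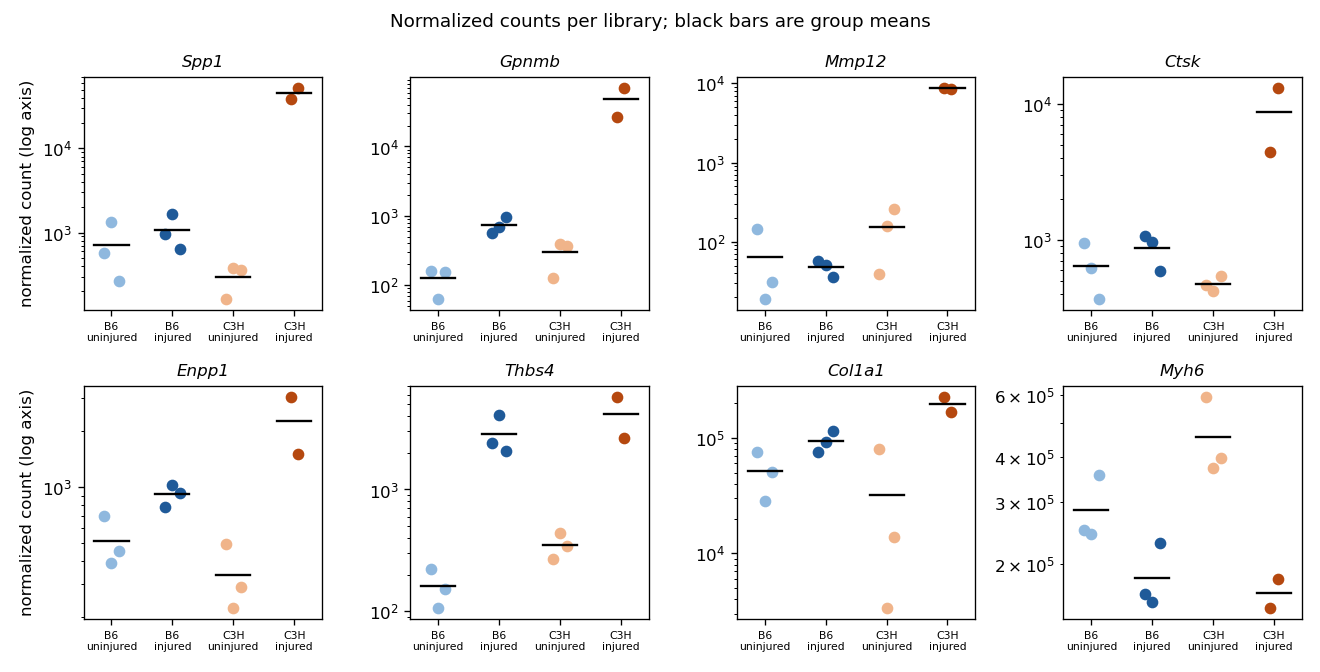
Normalised counts per library (vertical axes, log scale) of 8 named genes in the 4 groups, with 1 point per library and black bars at group means. Spp1 had a mean of 45644 in the C3H injured libraries against 1086 in the B6 injured ones, and Thbs4 rose in both strains.

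The next comparison asked the same of C3H hearts, where 4527 genes passed, 2253 up and 2274 down. Of the former 1890 and of the latter 1638 changed by over 2-fold. Genes of macrophages and of bone-resorbing cells had some of the greatest increases. Spp1 rose by 7.34 (SE 0.59, adjusted p = 2.09e-05), from a mean of 298 to 45644. Gpnmb, a glycoprotein of macrophages and osteoclasts, rose by 7.35 (SE 0.56, adjusted p = 1.56e-05), from 296 to 48437. Of 21 macrophage and monocyte markers, 17 rose and 0 fell (median 2.79, adjusted p = 2.73e-11, and adjusted p = 0.184 with an estimated correlation), 18 adjusted over the list alone. Lyz2, the macrophage lysozyme, rose by 2.99 (SE 0.33, adjusted p = 0.000113). Of 14 osteoclast genes 10 rose (median 3.22, adjusted p = 1.59e-07, and adjusted p = 0.184 with an estimated correlation), 13 adjusted over the list alone. Acp5, the tartrate-resistant acid phosphatase, rose by 4.81 (SE 0.63, adjusted p = 0.000327) and Atp6v0d2, a proton pump subunit, by 6.58 (SE 0.78, adjusted p = 0.000184). The count fell to 2801 without C3H injured library 1 (1375 up, 1426 down) and to 1708 without C3H injured library 2 (990 up, 718 down). It was 1662 up and 1456 down without C3H uninjured library 3, and 2011 up and 2645 down with quantile normalization.

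Part of the matrix genes rose with them in C3H. Of the 25 extracellular matrix genes, 23 rose over all genes and 24 adjusted over the list alone (median 3.06, adjusted p = 1.26e-10, and adjusted p = 0.337 with an estimated correlation). Postn, a matricellular protein of activated fibroblasts, rose by 3.41 (SE 0.66, adjusted p = 0.00282), Col12a1 by 5.83 (SE 1.01, adjusted p = 0.00166) and Fmod by 4.86 (SE 0.60, adjusted p = 0.000237). Of 22 matrix remodelling genes 17 rose, 19 adjusted over the list alone (median 2.33, adjusted p = 6.22e-10, and adjusted p = 0.184 with an estimated correlation). The macrophage elastase Mmp12 was at 6.18 (SE 0.80, adjusted p = 0.000318) and P4ha3, a collagen prolyl hydroxylase, at 4.71 (SE 0.75, adjusted p = 0.00101). Of 23 myofibroblast and TGF-beta genes 16 rose, 18 adjusted over the list alone (median 1.47, adjusted p = 3.99e-07, and adjusted p = 0.279 with an estimated correlation). Ltbp2, a TGF-beta binding protein, rose by 6.10 (SE 0.74, adjusted p = 0.000203) and Runx1 by 3.98 (SE 0.34, adjusted p = 2.64e-05). Of 18 fibroblast markers 8 rose and 1 fell on either adjustment (median 0.95, adjusted p = 0.00589, and adjusted p = 0.498 with an estimated correlation). Here Col1a1 was at 3.65 (SE 0.94, adjusted p = 0.0124). Of 12 chondrogenic genes 6 rose on either adjustment (median 1.29, adjusted p = 0.00687, and adjusted p = 0.261 with an estimated correlation). The cartilage collagen gene Col11a1 was at 7.31 (SE 0.85, adjusted p = 0.000163) and aggrecan, Acan, at 6.17 (SE 0.99, adjusted p = 0.00108). The chondrogenic median was 0.81 after quantile normalization and 1.94 without C3H uninjured library 1. That of fibroblast markers was 0.62 without C3H uninjured library 2. The Col1a1 call was lost without C3H injured library 1 (adjusted p = 0.0757) or C3H injured library 2 (0.0637). It was also lost with only the groups compared (adjusted p = 0.0585).

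Genes of bone formation and of mineral balance moved both ways in C3H. Of the 15 osteogenic genes tested, which did not include Sp7, Bglap, Ibsp, Dmp1 or Phex, 3 rose and 2 fell on either adjustment. The list as a whole did not pass (median 0.37, adjusted p = 0.409, and adjusted p = 0.629 with an estimated correlation). Its median was -0.07 after quantile normalization. Those that rose were Spp1, Tnn (6.55, SE 0.99, adjusted p = 0.000757) and Runx2 (2.63, SE 0.29, adjusted p = 0.000114). Those that fell were Alpl, the tissue-nonspecific alkaline phosphatase, at -1.08 (SE 0.30, adjusted p = 0.0178) and Bmp4 at -0.92 (SE 0.27, adjusted p = 0.0239). Of 15 mineralization inhibitor and phosphate genes 4 rose and 2 fell on either adjustment (median 0.66, adjusted p = 0.180, and adjusted p = 0.337 with an estimated correlation). Enpp1 rose by 2.75 (SE 0.38, adjusted p = 0.000451) and the phosphate transporter gene Slc20a1 by 1.34 (SE 0.30, adjusted p = 0.00567). The Alpl call was lost without C3H uninjured library 3 (adjusted p = 0.0543) or C3H injured library 2 (0.219), the last with a value of -0.68. This call was also lost with only the groups compared (adjusted p = 0.0584) or with edgeR without C3H uninjured library 1 (0.0538). That of Slc20a1 was lost without C3H injured library 1 (adjusted p = 0.0604).

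Part of the metabolic and cardiomyocyte genes fell in injured C3H regions. All 25 oxidative phosphorylation and TCA cycle genes fell on either adjustment (median -1.75, adjusted p = 7.90e-13, and adjusted p = 0.261 with an estimated correlation). The cytochrome oxidase subunit Cox7a1 was at -2.59 (SE 0.42, adjusted p = 0.00112) and the complex I subunit Ndufa1 at -2.07 (SE 0.39, adjusted p = 0.00266). Of 23 fatty acid oxidation genes 15 fell, 18 adjusted over the list alone (median -1.57, adjusted p = 6.22e-10, and adjusted p = 0.184 with an estimated correlation). Fabp3, the heart fatty acid binding protein, was at -2.32 (SE 0.40, adjusted p = 0.00158) and Acadm at -2.14 (SE 0.30, adjusted p = 0.000492). Of 20 glycolysis and hypoxia genes 10 fell and 4 rose, 12 and 4 adjusted over the list alone (median -0.86, adjusted p = 0.0429, and adjusted p = 0.447 with an estimated correlation). With the preset correlation this call was lost without C3H uninjured library 1 or 3, or C3H injured library 2 (adjusted p up to 0.0655). It was also lost with TMM rescaling (adjusted p = 0.0587) or a random block (0.0538), with the cause untested. The median was -0.55 after quantile normalization. Those that rose included the lactate exporter gene Slc16a3 by 1.71 (SE 0.44, adjusted p = 0.0121) and the carbonic anhydrase gene Car9 by 2.01 (SE 0.70, adjusted p = 0.0466). Of 24 cardiomyocyte markers 16 fell, 17 adjusted over the list alone (median -1.25, adjusted p = 3.82e-07, and adjusted p = 0.184 with an estimated correlation). After quantile normalization their median was -0.69. Myh6 fell by 1.43 (SE 0.45, adjusted p = 0.0307). With quantile normalization it was at -0.36. The call was lost with quantile normalization (adjusted p = 0.529), with only the groups compared (0.160) or with the animal as a block (0.0550). Leaving out 1 library also ended the Myh6 call, without C3H uninjured library 1 (adjusted p = 0.0662), C3H uninjured library 3 (0.0587), C3H injured library 1 (0.166) or C3H injured library 2 (0.114). The Slc16a3 call was lost without C3H injured library 1 (adjusted p = 0.0826) or C3H injured library 2 (0.0594). The Car9 call was lost without C3H uninjured library 2 (adjusted p = 0.124), C3H uninjured library 3 (0.0767), C3H injured library 1 (0.207) or C3H injured library 2 (0.145). It was also lost with a pseudocount of 0.5 (adjusted p = 0.0554) or with quantile normalization (0.0689).

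Some of the cytokine, interferon and proliferation genes rose in C3H. Of 24 inflammatory cytokine genes 11 rose, 12 adjusted over the list alone (median 2.03, adjusted p = 6.49e-06, and adjusted p = 0.261 with an estimated correlation). Il1rn, the interleukin 1 receptor antagonist, was at 6.63 (SE 0.60, adjusted p = 3.46e-05) and Ccl3 at 4.19 (SE 0.72, adjusted p = 0.00160). Of 24 cell cycle genes 14 rose and 1 fell, 15 and 1 adjusted over the list alone (median 1.63, adjusted p = 0.000102, and adjusted p = 0.498 with an estimated correlation). The proliferation marker Mki67 was at 2.48 (SE 0.58, adjusted p = 0.00741) and Bub1b at 2.72 (SE 0.72, adjusted p = 0.0140). Of 22 interferon response genes 7 rose, 8 adjusted over the list alone (median 0.75, adjusted p = 0.0129, and adjusted p = 0.635 with an estimated correlation). Mx1 was at 3.18 (SE 0.59, adjusted p = 0.00224) and Irf7 at 1.76 (SE 0.60, adjusted p = 0.0434). Of 22 Wnt genes 7 rose and 1 fell on either adjustment (median 0.81, adjusted p = 0.0129, and adjusted p = 0.438 with an estimated correlation). The Wnt antagonist gene Dkk2 was at 4.10 (SE 0.83, adjusted p = 0.00362) and Sfrp2 at 3.40 (SE 0.70, adjusted p = 0.00394). The Wnt median was 0.31 after quantile normalization and 0.44 and 1.22 without C3H injured libraries 1 and 2. That of interferon genes was 0.18 and 1.20 without C3H injured libraries 1 and 2. The list calls were lost for Wnt without C3H injured library 1 (adjusted p = 0.142) and for interferon without C3H uninjured library 2 or C3H injured library 1 (adjusted p up to 0.533). Single calls were lost for Mki67 without C3H injured library 1 (adjusted p = 0.0634) and Bub1b without C3H injured library 1 (adjusted p = 0.103) or C3H injured library 2 (0.0564). The Irf7 call was lost without C3H uninjured library 2 (adjusted p = 0.128), C3H injured library 1 (0.279) or C3H injured library 2 (0.0715), and that of Dkk2 without C3H injured library 1 (adjusted p = 0.0526). The Irf7 call was also lost without trend (adjusted p = 0.0731), with array weights (0.0565), with gene-by-gene array weights (0.0505), with only the groups compared (0.0699) or with edgeR without C3H uninjured library 1 (0.0773). That of Bub1b was also lost with only the groups compared (adjusted p = 0.0699), and its value was 1.72 without C3H uninjured library 2.

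Among other genes in C3H, the stress-induced transcription factor Atf3 rose by 3.47 (SE 0.30, adjusted p = 2.97e-05) and vimentin, Vim, by 2.26 (SE 0.40, adjusted p = 0.00185). The cardiac stress list had 4 genes up and 1 down on either adjustment and did not pass (median 0.07, 0.14 after quantile normalization, adjusted p = 0.322, and adjusted p = 0.629 with an estimated correlation). Npy, neuropeptide Y, rose by 8.13 (SE 1.20, adjusted p = 0.000667), from a mean of 3.14 to 627. The lipopolysaccharide receptor gene Tlr4 rose by 1.37 (SE 0.33, adjusted p = 0.00861). The genes that fell furthest under the naming rule were the homeobox genes Irx1 (-4.27, SE 0.92, adjusted p = 0.00499) and Irx2 (-4.42, SE 0.98, adjusted p = 0.00592). They were followed by Igsf1 (-3.25, SE 0.81, adjusted p = 0.0106) and the crystallin gene Cryba4 (-2.84, SE 0.67, adjusted p = 0.00803). Nnt, the mitochondrial transhydrogenase, fell by 1.48 (SE 0.26, adjusted p = 0.00179). Calls were lost without C3H injured library 2 for Tlr4 (adjusted p = 0.0958), Irx2 (adjusted p = 0.0736), Igsf1 (adjusted p = 0.157) and Cryba4 (adjusted p = 0.111). That of Igsf1 was also lost with only the groups compared (adjusted p = 0.0591). Igsf1 was at -1.72 without C3H injured library 2 and at -4.77 without C3H injured library 1. Quantile normalization moved the median over all genes in C3H from 0.01 to -0.11.

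Across all 14751 genes the injury effects of the strains, which shared no library, had a Pearson r of 0.691 (jackknife SE 0.0831) and a Spearman rho of 0.753. The sign was the same in 80.2% of genes. Of the 4527 genes called in C3H, 96.0% had the same sign in B6. These are correlations across genes, which are not independent replicates. When 1 library was left out, r lay between 0.615 (without B6 uninjured library 3) and 0.706.

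**Figure D2:**
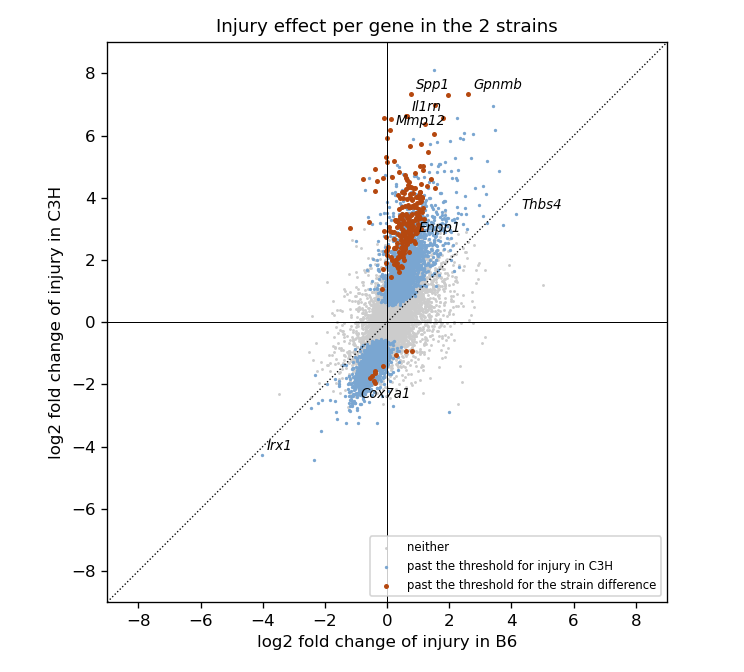
Log2 fold change of injury per gene in B6 (horizontal axis) and in C3H (vertical axis), with 1 point per gene tested. Points are blue for genes past the threshold in C3H and red for those past the threshold for the difference between the strains. Red points lie mostly above the dotted line of equal change (221 of 231 in the planned fit, and 581 of 777 with the animal as a random block).

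Whether the injury effect differed between the strains was tested directly, as the C3H effect minus the B6 effect. Some genes of the macrophage, osteoclast and matrix remodelling lists had the larger increases in C3H. On that side 221 genes were past the threshold, against 10 on the other. This balance varied between fits. The genes on these sides were 581 and 196 with the animal as a random block, 437 and 54 with a fixed block and 543 and 179 with DESeq2. They were 530 and 217 with array weights, 429 and 117 with weights gene by gene and 400 and 63 with edgeR and the block. Without trend they were 150 and 2. Spp1 had the difference 6.56 (SE 0.79, adjusted p = 0.00394) and the zinc transporter gene Slc39a2 6.68 (SE 1.08, adjusted p = 0.0115). Tnn had 6.43 (SE 1.32, adjusted p = 0.0318) and Mmp12 6.08 (SE 1.08, adjusted p = 0.0172). Il1rn followed with 6.02 (SE 0.80, adjusted p = 0.00516) and Col11a1 with 5.36 (SE 1.15, adjusted p = 0.0391). The collagenase gene Mmp13 had 4.58 (SE 0.85, adjusted p = 0.0218) and Acp5 3.92 (SE 0.84, adjusted p = 0.0403). Ctsk, the osteoclast protease cathepsin K, had 3.51 (SE 0.62, adjusted p = 0.0166) and Lyz2 2.51 (SE 0.44, adjusted p = 0.0162). Runx1 had 2.86 (SE 0.46, adjusted p = 0.0113), Atf3 2.85 (SE 0.41, adjusted p = 0.00589) and Runx2 1.87 (SE 0.39, adjusted p = 0.0337). On the other side were the TNF family receptor gene Tnfrsf12a at -1.70 (SE 0.38, adjusted p = 0.0492) and the cardiac transcription factor Nkx2-5 at -1.57 (SE 0.31, adjusted p = 0.0264). The BMP signalling inhibitor Smad6 was at -1.55 (SE 0.31, adjusted p = 0.0296), Pacsin3 at -1.48 (SE 0.30, adjusted p = 0.0318) and Mlycd, malonyl-CoA decarboxylase, at -1.24 (SE 0.28, adjusted p = 0.0469). Of these 18 genes past the threshold, only Spp1 kept its call whichever library was left out. The calls lost were 12 without B6 uninjured library 1 (adjusted p 0.0541 to 0.124), 5 without B6 uninjured library 2 (0.0639 to 0.0984), 3 without B6 uninjured library 3 (0.0526 to 0.0629). They were 10 without B6 injured library 1 (0.0600 to 0.129), 7 without B6 injured library 2 (0.0565 to 0.122) and 10 without B6 injured library 3 (0.0506 to 0.0975). For C3H they were 5 without uninjured library 1 (0.0515 to 0.0632), 5 without uninjured library 2 (0.0531 to 0.0755), 10 without uninjured library 3 (0.0526 to 0.132), 8 without injured library 1 (0.0556 to 0.119) and 17 without injured library 2 (0.0600 to 0.354). The count of 231 genes became 83 without B6 uninjured library 1, 108, 144 and 107 without B6 injured libraries 1, 2 and 3, 108 without C3H uninjured library 3 and 10 without C3H injured library 2. Without trend 7 of the 18 calls were lost, those of Nkx2-5, Pacsin3, Tnn, Col11a1, Mlycd, Acp5 and Tnfrsf12a (adjusted p 0.0577 to 0.0942). The calls of Tnn (adjusted p = 0.0949) and Col11a1 (adjusted p = 0.0541) were lost with edgeR. Those of Acp5 (adjusted p = 0.0722), Mlycd (adjusted p = 0.0525) and Tnfrsf12a (adjusted p = 0.0506) were lost with edgeR without C3H uninjured library 1, and that of Tnfrsf12a with a pseudocount of 0.5 (adjusted p = 0.0514). With the animal as a block the count was 491, of which 226 were among the 231.

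As groups, osteoclast genes had a median difference of 2.58 (adjusted p = 8.24e-11, and adjusted p = 0.121 with an estimated correlation). Of its 14 genes 3 passed over all genes and 10 adjusted over the list alone. Macrophage and monocyte markers had 1.69 (adjusted p = 1.98e-14, and adjusted p = 0.121 with an estimated correlation), with 8 of 21 and 13 on these adjustments. Matrix remodelling genes had 1.47 (adjusted p = 4.84e-10, and adjusted p = 0.184 with an estimated correlation), with 4 of 22 and 9. The extracellular matrix list had a median of 2.03 with 24 of 25 genes positive (adjusted p = 3.77e-09, and adjusted p = 0.430 with an estimated correlation). But 0 of its genes passed on either adjustment. Inflammatory cytokines had 1.63 (adjusted p = 1.53e-05, and adjusted p = 0.288 with an estimated correlation), with 1 gene over all genes and 3 adjusted over the list alone. The cell cycle had 0.88 (adjusted p = 0.00420, and adjusted p = 0.669 with an estimated correlation), with 0 on both. Myofibroblast genes had 0.57 (adjusted p = 0.00328, and adjusted p = 0.574 with an estimated correlation), with 1 and 6. On the other side, oxidative phosphorylation genes had -0.96 (adjusted p = 4.84e-10, and adjusted p = 0.315 with an estimated correlation), with 0 on both. Fatty acid oxidation genes had -0.89 (adjusted p = 8.27e-08, and adjusted p = 0.184 with an estimated correlation), with 1 on both. Cardiomyocyte markers had -0.83 (adjusted p = 9.82e-06, and adjusted p = 0.121 with an estimated correlation), with 0 on both. Endothelial markers had -0.54 (adjusted p = 0.00420, and adjusted p = 0.288 with an estimated correlation), with 0 on both. Epicardial markers had -0.75 (adjusted p = 0.0170, and adjusted p = 0.579 with an estimated correlation), with 0 on both. The preset-correlation call was lost for myofibroblast genes without B6 uninjured library 1 or C3H uninjured library 2 or C3H injured library 1 (adjusted p up to 0.180). It was lost for the cell cycle without B6 uninjured library 1 or C3H uninjured library 2 or C3H injured library 1 (adjusted p up to 0.174) and for epicardial markers without B6 uninjured library 1 or C3H injured library 2 (adjusted p up to 0.204). Median differences without 1 library were 1.09 without B6 injured library 3 and 1.02 without C3H injured library 1 for cytokines and 0.55 without B6 uninjured library 1, 0.46 without C3H uninjured library 2 and 0.53 without C3H injured library 1 for the cell cycle. They were 0.34 and 0.37 without B6 uninjured libraries 1 and 3 and 0.29 without C3H injured library 1 for myofibroblast genes, -0.32 without C3H uninjured library 1 and -0.30 without C3H injured library 2 for endothelial and -1.50 without B6 uninjured library 2 and -0.49 without C3H injured library 2 for epicardial markers. With the animal as a fixed block 17 lists passed with the preset correlation in place of 12. The 5 gained were those of interferon response (adjusted p = 0.00306), fibroblast (adjusted p = 0.00420), Wnt (adjusted p = 0.0299), glycolysis (adjusted p = 0.0488) and atrial genes (adjusted p = 0.0488).

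Several genes of matrix and mineral balance had differences that did not pass. Enpp1 had 1.88 (SE 0.51, adjusted p = 0.104), Postn 2.35 (SE 0.88, adjusted p = 0.245) and the matricellular gene Thbs2 1.75 (SE 0.52, adjusted p = 0.143). With the animal as a block these 3 passed (adjusted p = 0.0206, 0.0468 and 0.0356), while Runx2 no longer did (adjusted p = 0.0520), nor with edgeR and the block (adjusted p = 0.0525). Col1a1 had 2.68 (SE 1.26, adjusted p = 0.366), Alpl -1.17 (SE 0.40, adjusted p = 0.198), Tlr4 0.61 (SE 0.44, adjusted p = 0.579) and Nnt -0.81 (SE 0.35, adjusted p = 0.317). The osteogenic list did not pass (adjusted p = 0.665, and adjusted p = 0.768 with an estimated correlation). Its median was -0.31, and its mean and test were positive (mean 0.68).

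**Figure D3:**
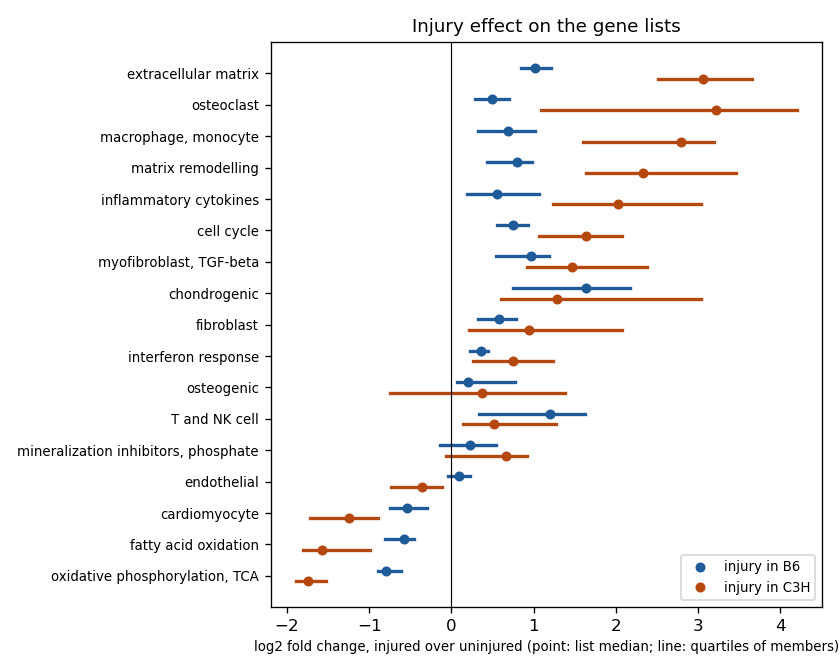
Median log2 fold change of the injured over the uninjured regions (horizontal axis) for 17 gene lists, in B6 (blue) and C3H (orange), with lines from the lower to the upper quartile of the members. The extracellular matrix median was 1.02 in B6 and 3.06 in C3H, and that of osteogenic genes in C3H changed its sign after quantile normalization.

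Uninjured regions of the same hearts were compared between the strains to describe how they differed away from the injury. Matrix, cytokine and interferon response lists were lower in C3H with the preset correlation only, and few of their genes passed. Postn was at -2.73 (SE 0.59, adjusted p = 0.0276), with a mean of 3854 in C3H and 20390.4 in B6. Its call was lost without B6 uninjured library 1 (adjusted p = 0.135), B6 uninjured library 2 (0.0649), C3H uninjured library 2 (0.0540) or C3H uninjured library 3 (0.0805). This call was also lost without trend (adjusted p = 0.0520), with edgeR (0.0555) or with only the groups compared (0.0802). The extracellular matrix list had a median of -1.21 with all 25 genes lower (adjusted p = 4.25e-07, and adjusted p = 0.559 with an estimated correlation). Of them 1 passed over all genes and 9 adjusted over the list alone. Matrix remodelling genes had -0.81 (adjusted p = 0.000298, and adjusted p = 0.559 with an estimated correlation), with 2 lower on the former and 6 on the latter adjustment. Inflammatory cytokines had -1.26 (adjusted p = 9.17e-06, and adjusted p = 0.559 with an estimated correlation), with 2 and 9. Interferon response genes had -0.86 (adjusted p = 7.68e-08, and adjusted p = 0.559 with an estimated correlation), with 3 and 9. Macrophage markers had -0.88 (adjusted p = 2.81e-06, and adjusted p = 0.559 with an estimated correlation), with 5 and 9 lower. Cell cycle genes had -0.90 (adjusted p = 3.48e-05, and adjusted p = 0.559 with an estimated correlation), with 0 on both. Medians without 1 library were -1.83 and -0.56 without C3H uninjured libraries 1 and 2 for the extracellular matrix, -0.43 without C3H uninjured library 2 for matrix remodelling and -0.57 without B6 uninjured library 1 and -0.37 without C3H uninjured library 2 for the cell cycle.

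A further 6 lists passed with the preset correlation in uninjured regions. Myofibroblast genes had a median of -0.15 (adjusted p = 0.0412, and adjusted p = 0.581 with an estimated correlation) and fibroblast markers -0.43 (adjusted p = 0.0343, and adjusted p = 0.559 with an estimated correlation). Higher medians in C3H were those of epicardial markers (0.77, adjusted p = 0.0103, and adjusted p = 0.559 with an estimated correlation) and cardiac stress genes (0.58, adjusted p = 0.0127, and adjusted p = 0.559 with an estimated correlation). So were those of Schwann cell markers (0.57, adjusted p = 0.0412, and adjusted p = 0.559 with an estimated correlation) and cardiomyocyte markers (0.33, adjusted p = 0.0343, and adjusted p = 0.559 with an estimated correlation). All 6 calls were lost without 1 library or another. They were lost for myofibroblast genes without B6 uninjured library 1 or 3, or C3H uninjured library 2 or 3 (adjusted p up to 0.433) and for fibroblasts without B6 uninjured library 1 or 3, or C3H uninjured library 2 (adjusted p up to 0.467). Calls were also lost for epicardial markers without B6 uninjured library 1 or 3 (adjusted p up to 0.192) and for stress genes without B6 uninjured library 3 (adjusted p = 0.0926). The others were lost for Schwann cells without B6 uninjured library 1 or 3, or C3H uninjured library 1 or 3 (adjusted p up to 0.163) and for cardiomyocytes without B6 uninjured library 1, or C3H uninjured library 1 or 3 (adjusted p up to 0.222). Medians of myofibroblast genes were -0.43 without B6 uninjured library 2 and -0.46 and -0.23 without C3H uninjured libraries 1 and 2. Those of fibroblast markers were -0.22 without B6 uninjured library 1 and -0.69 and -0.16 without C3H uninjured libraries 1 and 2, and those of stress genes 0.93 and 0.38 without C3H uninjured libraries 1 and 3. The median of cardiomyocyte markers was 0.15 without B6 uninjured library 1 and 0.21 without C3H uninjured library 1, and that of epicardial markers 0.36 without B6 uninjured library 1. After TMM rescaling 8 lists passed in place of 12, and so did 8 with the animal as a random block. In both cases those lost were of myofibroblast, fibroblast, Schwann cell and cardiomyocyte genes. Adjusted p with the block was 0.0514, 0.0553, 0.0872 and 0.0514 in this order.

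In total 458 genes passed between the uninjured regions, 194 higher and 264 lower in C3H. DESeq2 gave 375 and 541, only the groups compared 90 and 101, and edgeR 139 and 156 without C3H uninjured library 1. In limma without C3H uninjured library 1 they were 125 and 236. The count was 213 without B6 uninjured library 1, 235 without B6 uninjured library 2, 788 without B6 uninjured library 3, 297 without C3H uninjured library 2 and 246 without C3H uninjured library 3. The greatest differences under the naming rule held sex-linked genes, Xist at 8.23 (SE 0.40, adjusted p = 3.85e-07) and Ddx3y at -9.66 (SE 0.28, adjusted p = 2.30e-09). They also held Eif2s3y (1 read over the C3H libraries, B6-to-C3H ratio 3465, 95% counting interval 621 to 136914) and Uty (2 reads, ratio 686, 189 to 5674). Without C3H uninjured library 3 these ratios were 2203 and 436. Eif2s3y had 0 reads without C3H uninjured library 1 (at least 840.2-fold lower), and Uty 0 without C3H uninjured library 2 (at least 314-fold lower). Among autosomal genes, the kallikrein gene Klk1b22 had 0 reads in B6 and was thus at least 131-fold higher in C3H. That bound was 50.9 without C3H uninjured library 2, 80.0 without B6 uninjured library 1 and 79.8 without B6 uninjured library 3. Gbp2b, a guanylate-binding protein gene, was at 6.59 (SE 0.58, adjusted p = 6.78e-05). The osteogenic list did not pass (adjusted p = 0.234, and adjusted p = 0.559 with an estimated correlation). Runx2 was at -0.82 (SE 0.26, adjusted p = 0.131) and Enpp1 at -0.65 (SE 0.34, adjusted p = 0.382). Spp1 was at -1.08 (SE 0.53, adjusted p = 0.340) and Alpl at 0.20 (SE 0.27, adjusted p = 0.766). Nppa was at 2.41 (SE 0.65, adjusted p = 0.0713) and Nnt at 0.79 (SE 0.23, adjusted p = 0.104). Col1a1 was at -1.62 (SE 0.84, adjusted p = 0.372), Myh6 at 0.67 (SE 0.40, adjusted p = 0.452) and Tlr4 at 0.04 (SE 0.29, adjusted p = 0.965).

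Injured regions were compared between the strains in the last comparison. Osteoclast, macrophage and matrix remodelling lists were higher in C3H, and mitochondrial lists lower, with the preset correlation only. Mmp12 was higher by 7.48 (SE 0.80, adjusted p = 0.000307) and Spp1 by 5.48 (SE 0.59, adjusted p = 0.000307), with Spp1 means of 45644 in C3H and 1086 in B6. Of 14 osteoclast genes 9 were higher, 11 adjusted over the list alone (median 2.13, adjusted p = 8.66e-11, and adjusted p = 0.338 with an estimated correlation). Of 21 macrophage markers 8 were higher, 11 adjusted over the list alone (median 1.01, adjusted p = 2.51e-05, and adjusted p = 0.410 with an estimated correlation). Matrix remodelling genes had a median of 0.51 with 6 of 22 higher on either adjustment (adjusted p = 0.000742, and adjusted p = 0.558 with an estimated correlation). The macrophage median was 0.54 without C3H injured library 2. The extracellular matrix list did not pass (median 0.72, adjusted p = 0.0520, and adjusted p = 0.882 with an estimated correlation), with 0 genes past the threshold. Col1a1 was at 1.06 (SE 0.94, adjusted p = 0.524) and Postn at -0.37 (SE 0.66, adjusted p = 0.764).

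Oxidative phosphorylation genes had a median of -1.01 in injured C3H against injured B6 regions, with 5 of 25 lower over all genes and 21 adjusted over the list alone (adjusted p = 8.66e-11, and adjusted p = 0.410 with an estimated correlation). Fatty acid oxidation genes had -1.01, with 9 of 23 and 14 (adjusted p = 1.75e-08, and adjusted p = 0.357 with an estimated correlation). Cardiomyocyte markers had -0.48, with 2 of 24 and 7 (adjusted p = 0.0161, and adjusted p = 0.410 with an estimated correlation). Interferon response genes had -0.64 (adjusted p = 0.00830, and adjusted p = 0.778 with an estimated correlation) and endothelial markers -0.36 (adjusted p = 0.0241, and adjusted p = 0.410 with an estimated correlation). The preset-correlation call was lost for cardiomyocytes without B6 injured library 3 or C3H injured library 1 (adjusted p up to 0.0722) and for interferon genes without B6 injured library 2 or C3H injured library 2 (adjusted p up to 0.581). It was lost for endothelium without B6 injured library 3 or C3H injured library 2 (adjusted p up to 0.129). The median of cardiomyocyte markers was -0.28 without C3H injured library 1, and that of interferon genes -0.42 without B6 injured library 2 and -1.08 and -0.20 without C3H injured libraries 1 and 2.

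In total 1042 genes passed between the injured regions, 549 higher and 493 lower in C3H. The count was 335 (214 higher) and 438 (281 higher) without B6 injured libraries 1 and 2, and 599 (362 higher) and 101 (57 higher) without C3H injured libraries 1 and 2. Weights gene by gene gave 1625 higher and 1851 lower, and only the groups compared 822 and 740. Quantile normalization gave 681 higher and 853 lower, DESeq2 974 and 1040 and array weights 2096 and 2400. Beside Mmp12, the greatest increases under the naming rule were those of Xist (9.77, SE 0.44, adjusted p = 2.72e-07) and Hal, histidine ammonia lyase (8.33, SE 0.80, adjusted p = 0.000140). Ifi44l, an interferon-induced gene with 0 reads in B6, was at least 225-fold higher in C3H, or 149 without B6 injured library 1 and 147 without B6 injured library 2. The greatest decreases included those of Ddx3y (-8.50, SE 0.31, adjusted p = 4.05e-08), Kdm5d (0 reads in C3H, at least 236-fold lower) and Eif2s3y (2 reads, B6-to-C3H ratio 1159.85, 95% counting interval 321 to 9581). The bound for Kdm5d was 129.9 without C3H injured library 1 and 106 without C3H injured library 2. Runx2 was higher by 1.05 (SE 0.29, adjusted p = 0.0494). This call was lost without B6 injured library 1 (adjusted p = 0.168), B6 injured library 2 (0.118), B6 injured library 3 (0.0783), C3H injured library 1 (0.139) or C3H injured library 2 (0.411). It was also lost with a pseudocount of 0.5 (adjusted p = 0.0507), with no filter (0.0534), with TMM rescaling (0.0522) or with the animal as a random block (0.0711). Enpp1 (1.24, SE 0.38, adjusted p = 0.0729), Alpl (-0.97, SE 0.30, adjusted p = 0.0744) and Nppa (1.63, SE 0.72, adjusted p = 0.194) did not pass. Neither did Tlr4 (0.65, SE 0.33, adjusted p = 0.254), Myh6 (-0.13, SE 0.45, adjusted p = 0.888) and Nnt (-0.03, SE 0.26, adjusted p = 0.966).

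**Figure D4:**
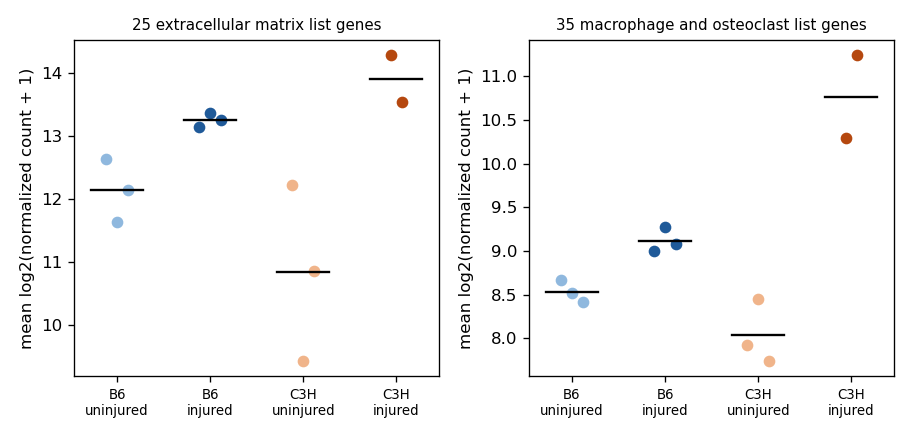
Mean log2(normalised count + 1) per library (vertical axes) over 25 extracellular matrix genes (left) and over 35 macrophage and osteoclast genes (right), with 1 point per library and black bars at group means. The mean score of the right panel rose by 0.58 (SE 0.28) in B6 and 2.72 (SE 0.31) in C3H.

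Of the genes past the threshold between strains, 70 were higher and 105 lower in C3H in both regions, and 9 went opposite ways. These regions came from the same animals. As above, sex and strain could not be told apart in these comparisons.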

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

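The tests of explanations in this part (cell shares, injury tissue in B6 uninjured regions, sex) were chosen only after the results were seen. All results here stood out because the injury effect differed between the strains by the interaction term, C3H minus B6.

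In all 231 genes differed, 221 with a positive difference (581 of 777 with the animal as a random block). Those with the larger increase in C3H included Spp1 (6.56), Slc39a2 (6.68), Tnn (6.43), Mmp12 (6.08), Il1rn (6.02), Col11a1 (5.36), Mmp13 (4.58), Acp5 (3.92), Ctsk (3.51), Runx1 (2.86), Atf3 (2.85), Lyz2 (2.51) and Runx2 (1.87). On the other side were Mlycd (-1.24), Pacsin3 (-1.48), Smad6 (-1.55), Nkx2-5 (-1.57) and Tnfrsf12a (-1.70). The count was 83 without B6 uninjured library 1, 108, 144 and 107 without B6 injured libraries 1, 2 and 3, 108 without C3H uninjured library 3 and 10 without C3H injured library 2. Without the last, of these 18 genes Spp1 alone kept its call (adjusted p 0.0600 to 0.354 for the others). Without trend 7 of the 18 calls were lost.

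Lists that passed with the preset correlation, though 0 did with an estimated correlation, had median differences of 2.58 (osteoclast), 2.03 (extracellular matrix), 1.69 (macrophage and monocyte), 1.63 (inflammatory cytokines), 1.47 (matrix remodelling), 0.88 (cell cycle) and 0.57 (myofibroblast and TGF-beta). Those with a negative difference were oxidative phosphorylation (-0.96), fatty acid oxidation (-0.89), cardiomyocyte (-0.83), epicardial (-0.75) and endothelial markers (-0.54). Without 1 library the median differences were 1.09 without B6 injured library 3 and 1.02 without C3H injured library 1 for cytokines, 0.55 without B6 uninjured library 1, 0.46 without C3H uninjured library 2 and 0.53 without C3H injured library 1 for the cell cycle and 0.34 and 0.37 without B6 uninjured libraries 1 and 3 and 0.29 without C3H injured library 1 for myofibroblast genes. Those of epicardial markers were -1.50 without B6 uninjured library 2 and -0.49 without C3H injured library 2, and those of endothelial markers -0.32 without C3H uninjured library 1 and -0.30 without C3H injured library 2. The estimated-correlation adjusted p of these 12 lists lay between 0.121 (osteoclast) and 0.669 (cell cycle).

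The pattern weighed is the larger injury response of the 35 macrophage and osteoclast list genes in C3H, whose mean score rose by 2.14 (SE 0.41) more than in B6. A lower cardiomyocyte share in C3H injured pieces would raise markers of other cells alike. These genes exceeded 59 markers of T, NK, B, endothelial, mural and epicardial cells by 2.57 (SE 0.65). Both sets were picked after values were seen, so this excludes nothing. Injury tissue already present in the B6 uninjured regions would leave the injured regions of the strains alike, but C3H was higher there by 1.65 (SE 0.308). For the 25 extracellular matrix genes this cause cannot be told apart from a larger response. Injured regions differed by 0.653 (SE 0.75) and uninjured ones by -1.30 (SE 0.671), neither more than 2 SE from 0. The former difference was 0.278 and 1.03 without C3H injured libraries 1 and 2. The latter was -1.996 (SE 0.506) and -0.597 (SE 0.493) without C3H uninjured libraries 1 and 2. Sex and strain stay open and cannot be parted, as all 5 C3H libraries carried more Xist than any B6 one.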

How the results depend on the processing

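The edgeR fits with the replicate block or without C3H uninjured animal 1 and the gene by gene array weights were chosen after the data were seen. So were left-out libraries for lists, scores and bounds, and the fixed block and quantile medians for lists. The gene count for injury in B6 (2) was 45 with DESeq2, 16 with a random and 20 with a fixed block of animals, and 26 with edgeR and the block. It was 2708 with array weights and 224 with gene by gene array weights. The former weights stopped before convergence and gave B6 injured library 2 a weight of 13.7, against 4.58 gene by gene, so that 2708 rests on a fit that had not converged. The interaction count (231) was 152 without trend, 747 and 546 with these weights, 722 with DESeq2, 777 with the random and 491 with the fixed block, and 463 with edgeR and the block. Between uninjured regions the count (458) was 916 with DESeq2, 191 with only the groups compared, which leaves fewer residual degrees of freedom, and 295 with edgeR without C3H uninjured animal 1. Between injured regions (1042) it was 4496 and 3476 with the weights and 2014 with DESeq2. Leaving out 1 library, which lowers the power, gave 1 to 2 in B6, 1708 to 4639 in C3H (4527), 10 to 272 for the interaction, and 213 to 788 and 101 to 871 between strains. All other alternatives kept these counts within 1.5 times. The agreement of the injury effect between strains (0.691) was 0.797 with a mean normalized count of at least 50. With an estimated correlation 0 lists passed in each comparison, against 18, 15, 12, 12 and 8, and leaving out 1 library gave 7 to 12 lists between uninjured regions. The causes of these changes were not tested where none is stated.

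Of the values of genes named by rule under the alternatives, 760 of 813 kept their direction and call in B6 (6 lost and 42 gained a call), 1085 of 1167 in C3H (57 and 18), 997 of 1137 for the interaction (107 and 25), 344 of 360 between uninjured (7 and 5) and 296 of 323 between injured regions (9 and 9). The rest changed sign, all of them without a call. For injury in B6 these were Myh6 (0.00855 with quantile normalization), Des (0.27 with it, -0.19 to 0.00660 without 1 library), Alpl (-0.0806 to 0.18 without 1 library) and Msln (-0.28 to 2.14). For injury in C3H it was Lcn2, at -0.42 with edgeR on recovered reads, -0.0791 with the replicate block, fixed, -0.98 with edgeR without C3H uninjured animal 1, -0.22 with edgeR with replicate block and -1.20 to 2.93 without 1 library. For the strain difference of the injury effect they were Lcn2 (-0.22, -0.78 and -0.0185 with these edgeR fits, -0.97 to 3.16 without 1 library) and Mbp (-0.0709 with array weights). Without 1 library they were also Nppa (-1.35 to 0.0277), Alas2 (-1.92 to 0.28) and Kit (-0.24 to 0.86). For the strain difference in uninjured regions it was Tlr4, at -0.0133 with limma with array weights and -0.18 to 0.38 without 1 library. For the strain difference in injured regions they were Nnt (0.12 with quantile normalization, 0.0364 and 0.0177 with the weights, -0.16 to 0.11 without 1 library) and Myh6 (0.0607 with quantile normalization, 0.0494 with array weights, -0.27 to 0.0431 without 1 library). The causes were not tested. In C3H Jchain (adjusted p = 0.00554), Alas2 (adjusted p = 0.00641) and Cd4 (adjusted p = 0.0177) passed with the fixed block and not without it. For the interaction the fit of only the groups compared is the fit of all groups. Depth limited the folds of genes with at most 3 reads in a group, which are given as bounds or ratios.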

Other observations

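The tests in this part on blocked counts, on cardiomyocyte loss and on other splits of the samples were chosen only after the results were seen, and those on the spread of B6 libraries and on subendocardial genes before.

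Markers of vessels, lymphocytes and other cell types that no list call in C3H covered are given here, some with their medians after quantile normalization (QN). Of 16 endothelial markers 4 fell on either adjustment, Emcn (-0.85), Egfl7 (-0.89), Esam (-0.76) and Fabp4 (-1.38). The list did not pass (median -0.36, adjusted p = 0.0528, and adjusted p = 0.411 with an estimated correlation). T and NK cell markers had a median of 0.52 (QN -0.12), with 0 genes past the threshold (adjusted p = 0.380, and adjusted p = 0.657 with an estimated correlation). B cell markers had 0.18 (QN -0.41), with Cd22 at 5.29 past the threshold on either adjustment (adjusted p = 0.208, and adjusted p = 0.562 with an estimated correlation). Neutrophil markers had 0.86 with 1 gene up on either adjustment, Csf3r at 2.91 (adjusted p = 0.367, and adjusted p = 0.704 with an estimated correlation). Mast cell markers had 0.58 (QN 0.15) with 0 (adjusted p = 0.532, and adjusted p = 0.669 with an estimated correlation). Mural cell markers had 0.21 with 2 up and 3 down, 3 and 3 adjusted over the list alone (adjusted p = 0.960, and adjusted p = 0.979 with an estimated correlation). Epicardial markers had -0.17 (QN -0.32) with 0 (adjusted p = 0.897, and adjusted p = 0.964 with an estimated correlation). Schwann cell markers had -0.11 (QN -0.62) with 1 up, Mbp at 1.30, and 0 adjusted over the list alone (adjusted p = 0.897, and adjusted p = 0.964 with an estimated correlation). Atrial markers had -0.73 (QN -1.13) with 1 up and 2 down on either adjustment (adjusted p = 0.511, and adjusted p = 0.629 with an estimated correlation). Skeletal muscle markers had 0.14 (QN -0.34) with 1 down, Mylk4 at -1.95. Their test pointed down (adjusted p = 0.940, and adjusted p = 0.964 with an estimated correlation). Adipocyte markers had -0.84, or -0.27 with Car3 and Cfd at their bounds, with 2 of 5 down on either adjustment (adjusted p = 0.511, and adjusted p = 0.696 with an estimated correlation). Erythroid (3 genes, median -2.05), lung (2 genes, -1.22) and cartilage and bone markers (4 genes, 1.83, or 2.11 with Matn3 at its bound) were too few to test. Of the single genes here the naming rule covered Fabp4, Mbp and Mylk4, and the others were not refitted without 1 library. Calls were lost for Fabp4 without C3H uninjured library 3 (adjusted p = 0.0593), C3H injured library 1 (0.0545) or C3H injured library 2 (0.124), for Mbp without C3H uninjured library 1 (adjusted p = 0.0591), C3H uninjured library 2 (0.0915), C3H injured library 1 (0.0630) or C3H injured library 2 (0.238) and for Mylk4 without C3H injured library 2 (adjusted p = 0.0819). That of Mbp was also lost with quantile normalization (adjusted p = 0.0537) or with edgeR without C3H uninjured library 1 (0.0573). Over all the alternatives the value of Fabp4 lay between -1.64 and -0.88.

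In B6 the lists that did not pass and are not given above had medians of 0.09 (endothelial, QN 0.23, adjusted p = 0.655, and adjusted p = 0.785 with an estimated correlation) and -0.23 (neutrophil, QN -0.55, adjusted p = 0.982, and adjusted p = 0.992 with an estimated correlation). Others had 0.39 (mast cell, QN 0.12, adjusted p = 0.266, and adjusted p = 0.433 with an estimated correlation) and 0.20 (atrial, adjusted p = 0.325, and adjusted p = 0.433 with an estimated correlation). Glycolysis genes had -0.27 (QN 0.01, adjusted p = 0.143, and adjusted p = 0.460 with an estimated correlation). Schwann cell markers had 0.20 (QN -0.08, adjusted p = 0.221, and adjusted p = 0.532 with an estimated correlation) and skeletal muscle markers 0.33 (QN -0.08, adjusted p = 0.802, and adjusted p = 0.802 with an estimated correlation). Adipocyte markers had a median of -0.30 (QN -0.15) and a mean of 0.01 (adjusted p = 0.344, and adjusted p = 0.535 with an estimated correlation). Erythroid markers had -0.68 (QN -1.02), cartilage and bone markers 1.75 and lung markers 0.44 (QN -0.09, -0.03 with Sftpb at its bound), untested. Medians differed in sign from means or tests, in lists that did not pass, also for B cells (-0.15 and 0.14) and mast cells (-0.28 and 0.15) in the interaction. So they did for neutrophils (-0.21 and 0.22) and skeletal muscle (-0.08 and 0.41) in uninjured regions. In injured regions they did for mural cells (0.09 and -0.05), skeletal muscle (-0.25 and 0.28) and atrial markers (-0.23 and 0.05). With QN the medians were -0.34 for B and 0.01 for mast cells, -0.09 for neutrophils, 0.07 for skeletal muscle in uninjured regions and -0.04 for mural cells.

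The small number of genes past the threshold in B6 (2, against 4527 in C3H, and 1 to 2 against 1708 to 4639 without 1 library) was weighed next. Against B6 standard errors 5159 C3H fold changes passed, which cannot test a wider B6 spread, as both counts used a pooled spread. Differences between hearts were argued against as the whole cause, as 20 genes passed with the animal as a block, against 5151 in C3H. The spread may take part, as array weights gave 224 or, unconverged, 2708 genes and DESeq2 45. Another split of the B6 libraries (uninjured 1 and 2 with injured 1, against the others) called 1126 genes, which points to structure beside injury. Changes were smaller in B6 (median absolute change 0.330, SE 0.302, or 0.296 fitted alone, against 0.672, 0.338 and 0.316 in C3H). The cause stays open, as injury extent and the share of injured tissue were not measured.

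The fall of the homeobox genes Irx1, Irx2 and Irx5 in injured C3H regions, chosen after their values were seen, was weighed as well. Their mean score fell by 3.46 (SE 0.734) in C3H. In B6 it fell by 2.91 (SE 0.657), but 0 of the 3 genes passed in the planned fit (adjusted p = 0.322 for Irx1, 0.364 for Irx2 and 0.0584 for Irx5). Irx2 did not pass there with the animal as a block either (adjusted p = 0.133), and its normalised count in B6 uninjured library 3 (8.25) was below those in injured libraries 1 (14.7) and 3 (11.2). Loss of cardiomyocytes stays open. The 3 genes differed from the cardiomyocyte list by -2.19 (SE 0.802) in C3H and -2.43 (SE 0.717) in B6, but they were picked for their fall, so that this excludes nothing. Injured pieces with less subendocardial and conduction tissue remain a candidate explanation as well, which the test left open. The 5 genes set for this test and in the table (Irx3, Gja5, Cntn2, Kcne1, Etv1) differed from the cardiomyocyte list by 0.0765 (SE 0.266) in C3H but by -0.814 (SE 0.238) in B6. The value in C3H was 0.00967 and 0.128 without C3H uninjured libraries 1 and 3, and -0.174 and 0.327 without C3H injured libraries 1 and 2. Among them Irx3 (-1.93) and Kcne1 (-2.52) fell in C3H and Gja5 (-0.14), Cntn2 (-2.30) and Etv1 (0.92) did not pass there. A change of these genes in the cardiomyocytes that remain stays open, as untested.

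Splits of 6 libraries into groups of 3 number 10, too few for a share under 0.05. For injury in B6 the real split gave 2 genes and the highest other 1126 (2 splits gave as many, the real one included), while the other splits that part all 3 pairs of regions gave 0 genes. For lists in B6 the real split gave 18 and the highest other 16, which also parts the 3 pairs (1 split, the real one, gave as many). Between uninjured regions the real split of strains gave 458 genes and the highest other 0 (1 split), and 12 lists against 12 (2 splits).

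Ribosomal protein genes took 0.832% (C3H uninjured library 1) to 1.91% (B6 uninjured library 1) of normalised counts, and the 10 most abundant genes of each library 8.19% (C3H injured library 2) to 13.7% (C3H uninjured library 1). Xist was between 1839.8 and 8478 in the C3H libraries and between 3.14 and 12.2 in the B6 libraries, and Ddx3y between 0.888 and 3.46 against 1429 to 2221.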
